A study of Mus musculus with 6 samples.

How the data were processed

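The analysis started from the deposited table of UMI counts (unique molecular identifiers, 1 per captured RNA molecule), which holds 19,954 gene symbols in 18,514 nuclei. That these values are counts is read from the deposited matrix, whose entries are whole numbers with totals that differ between nuclei. The deposited metadata add, per nucleus, the library, a batch number, the authors' major cell type and neuron subtype, and a mitochondrial fraction. The fraction is inferred to be mitochondrial UMIs over all UMIs, because in the deposited values it gives a whole number of mitochondrial UMIs, within 1e-06, for each of the 18,514 nuclei. Mitochondrially encoded genes themselves are absent from the deposited count table. The submitters' processing notes name Cell Ranger 2.2.0, Seurat 3 and the mouse builds mm10 and GRCm38. The thresholds used to keep nuclei, whether intronic reads were counted, whether counting used the strand, and what a batch number stands for are not given in the sources used here. The smallest number of genes per nucleus in the table was 197 and the largest mitochondrial fraction was 4.918%.

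Gene coordinates and biotypes came from GENCODE vM21 (GRCm38). Of the 19,954 symbols, 19,153 (96.0%) matched 1 annotated gene by symbol. Because the strand of counting is unknown, a gene that overlaps another annotated gene, on either strand, is reported as uncertain in which of the overlapping genes gave its reads.

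Counts were summed per sample within all nuclei, all neurons, excitatory neurons, inhibitory neurons, each of the 5 other major cell types, and each neuron subtype with at least 10 nuclei in every sample (24 of 38 subtypes). Subtypes were assigned to excitatory (22), inhibitory (15) or cholinergic (1) by a fixed rule on the summed counts of transmitter genes, which placed V1/V2b/Slit2 among the excitatory subtypes against what its name would give. Gene tests used edgeR 4.0.16 (quasi-likelihood F test on TMM-normalized counts, filterByExpr with a minimum count of 10), in R 4.3.3, comparing 3 TESS with 3 CON samples without a batch term. A gene was called at a Benjamini-Hochberg adjusted p below 0.05 within its class. Gene tests in neuron subtypes were adjusted within each subtype, with no adjustment across subtypes. Fold changes are log2 of TESS over CON, and their standard error (SE) is the fold change divided by the square root of F. Levels (CPM) are counts scaled by the TMM-normalized total of the genes tested in the class, as mean and standard deviation (SD) over 3 samples. With fewer genes tested this total is smaller and CPM are higher, so levels are not comparable between classes. CPM of summed samples, given with UMI counts, and immediate early gene levels of subtypes are over all UMIs of the class. Differences between cell classes were tested as interaction terms in edgeR with the sample as a block.

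The 30 gene lists and the rule for which genes are named were fixed before the data were examined. So were the tests and alternatives, except those said below to have been chosen afterwards. Each list with at least 5 measured members was tested against all other genes with camera of limma 3.58.1 on voom values, with a preset correlation between genes of 0.01, and again with an estimated correlation and with fry. List members were also counted after adjustment over the list alone. Of the 30 lists, 28 were tested in at least 1 class: immediate early, delayed activity-response, glucocorticoid-response, circadian clock, heat shock and chaperone, unfolded protein response, hypoxia and glycolysis, nuclear oxidative phosphorylation, cytosolic ribosomal protein, cholesterol synthesis, interferon-response, axon injury and regeneration, voltage-gated channel, glutamate receptor, GABA and glycine receptor, serotonin and dopamine receptor, neuron, myelinating oligodendrocyte, oligodendrocyte precursor, homeostatic and activated microglia, homeostatic and reactive astrocyte, endothelial, pericyte and fibroblast, ependymal, Schwann cell, and blood and peripheral immune cell genes. The mitochondrially encoded list had no gene in the table and the sex-linked list had too few measured members to test.

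The named genes of a class are those called with groups that do not overlap and a mean of at least 10 CPM, up to the 10 largest changes in each direction. Where fewer than 5 passed in a direction, those with the smallest p fill up to 5 and are said not to pass. List members that pass over all genes or over the list alone may also be named, and Fos, Fosb, Junb, Egr1, Arc, Npas4, Nr4a1, Htr1a and Drd1 are always given in neurons. Among subtypes, those with the most called genes, the largest and smallest immediate early gene changes, and the highest and lowest separability are named.

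The immediate early gene level of a subtype is log2 of the CPM summed over the 34 listed genes plus 10 CPM, compared with limma and adjusted over 24 subtypes. Shares of major cell types were compared with a two-sided exact permutation test, whose smallest possible p with 3 against 3 samples is 0.1, and numbers of nuclei per subtype with edgeR. Separability was measured in Python 3.11.15 with scikit-learn 1.9.0: for 11 subtypes with 20 or more nuclei in every sample, a random forest of 100 trees on 1000 variable genes was trained on 4 samples and scored on the held-out CON and TESS sample by the area under the ROC curve (AUC, 0.5 for no separation), over 9 held-out pairs and 5 draws of 20 nuclei per sample.

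Alternatives covered DESeq2's size factors inside edgeR, DESeq2 1.42.0 itself, no expression filter, the replicate number as a block, each sample left out in turn, thinning of the counts to the lowest sample total, removal of doublets, ribosomal genes or genes far higher in other classes, and other settings of the list, level, share and separability tests. Those chosen after the data were seen are the batch term, equal composition of the sums, removal of the 5% of neurons with the most UMIs, removal of genes 2 times higher in neurons from the other classes, and thinning of nuclei to 500 UMIs. The batch term leaves TESS 1 against CON 1 and CON 2, all in batch 3, to carry the group difference, and the lone TESS sample there is assumed to vary like the others. Scrublet, run per sample through scanpy 1.11.5, called 55 of 18,514 nuclei doublets (0.297%), too few for this loading, so doublets were in effect not removed by it.

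The gene test was tested on simulated data with the depths and spread of the real samples, in which fold changes were planted. In neurons it found 29.9% of genes changed 1.5-fold, 70.8% changed 2-fold and 98.5% changed 4-fold, with 4.4% false calls among its calls. In oligodendrocytes it found 20%, 54.5% and 95%, with 8.6% false calls, and in all nuclei summed 31.8%, 71.6% and 98.4%, with 10.2%. In microglia it found 3.1% of the 1.5-fold and 50% of the 2-fold changes. The interaction test gave 11 false among 89 calls for neurons against other nuclei and 2 false among 68 for excitatory against inhibitory neurons. The list test found 20 of 20 planted lists and called 0 of 436 others, but the simulated genes were drawn independently. The false calls it makes with correlated genes were therefore not measured. The subtype level test found 72 of 120 planted changes with 6 of 360 false calls. The subtype share test found 119 of 120 planted rises. Only rises among the 640 other shares counted as false, and there were 0, but those shares fall when the planted ones rise. Its false calls were therefore not measured, and its simulated samples had no spread beyond counting. Simulated nuclei without a group difference gave a mean AUC of 0.5096 at equal depth and 0.558 at depths in the ratio of the real samples' medians. These nuclei had neither the UMI totals of the real nuclei nor a spread between samples. With 200 genes planted 3-fold higher it was 0.9999.

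Counting limits come from 3 counts, the upper limit that a count of 0 allows, which was 1.15 to 3.05 CPM per sample in neurons. Depth and floors cover counting error only.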

Results

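The data are single-nucleus RNA counts from the lumbar spinal cord of wild-type C57BL/6 mice whose legs were paralysed by a severe contusion of the thoracic cord. Before collection the mice spent 30 min on a treadmill, either with targeted epidural electrical stimulation of the cord (TESS, 3 samples) or without it (CON, 3 samples, labelled paralyzed). The series describes TESS as restoring walking in the presence of agonists of the serotonin receptor 5-HT1a and the dopamine receptor D1. Whether the CON mice received the agonists is not clear from it. The tissue source is given as lumbar cord, while the extraction text names the thoracic injury site, and the lumbar label is followed here. Libraries were made with 10x version 2 chemistry from 5000 loaded nuclei each.

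The deposited table holds 18,514 nuclei in 6 major cell types, of which 6035 are neurons in 38 subtypes. The series text states 20,484 nuclei and 6171 neurons. CON 1, CON 2 and CON 3 held 3646, 3416 and 3780 nuclei with 4,003,227, 4,037,976 and 3,365,530 UMIs, and TESS 1, TESS 2 and TESS 3 held 2641, 2839 and 2192 nuclei with 2,891,177, 2,316,796 and 1,582,104 UMIs. The median nucleus had 646, 707 and 544.5 UMIs in the CON samples and 598, 478 and 424 in the TESS samples, so the TESS samples were shallower in total. CON 1, CON 2 and TESS 1 share batch 3, while CON 3, TESS 2 and TESS 3 are each the lone sample of batches 4, 2 and 1. For called genes and lists of the major classes the value inside batch 3, where TESS 1 stands against CON 1 and CON 2, is therefore given where it differs from the pooled one by over 1.5 times, and for some others. In neurons, pairs of samples of the same group differed by 1.69 to 6.42 times counting noise (chi-square per degree of freedom over genes). Pairs of a CON and a TESS sample differed by 3.03 to 6.11 times. The largest value of all was that of CON 1 against CON 2, the 2 CON samples of batch 3. The labels do not state that each sample is a separate animal, so p-values of genes, subtypes and shares measure the spread between these samples. Those of camera with the preset correlation also rest on the spread over genes, taken as nearly uncorrelated.

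The first question was which transcripts differ after TESS in the cord as a whole, with all nuclei of a sample summed. Of 21 measured immediate early genes, which are switched on within minutes of cell stimulation, 8 rose in TESS. Among them Per1, an immediate early and clock gene, rose 1.48 ± 0.18 (log2 fold change ± SE, n = 3 per group, adjusted p = 0.0012), from 19.5 ± 3.66 to 54.7 ± 7.45 CPM (mean ± SD), and Btg2, an antiproliferative immediate early gene, rose 1.85 ± 0.31 (adjusted p = 0.0119). The transcription factor genes Fos and Egr1 rose 1.61 ± 0.32 (0.98 inside batch 3) and 1.74 ± 0.34. Of 15 measured genes induced by glucocorticoid hormone 6 rose, among them Fkbp5, a co-chaperone of the glucocorticoid receptor, by 1.31 ± 0.25 and Nfkbia, the inhibitor of NF-kappaB, by 1.13 ± 0.21. As lists both groups lost their call with adjusted p = 0.181 with an estimated correlation. Nts, which encodes the peptide neurotensin, fell by 1.20 ± 0.18 (adjusted p = 0.00556), from 141 ± 33.7 to 61.9 ± 12.7 CPM.

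Of 13,391 genes tested, 34 rose and 67 fell, and the groups did not overlap in any of these 101 genes, against 20.7% of all genes tested and 10% given by chance. In every class a call with this few samples nearly requires groups that do not overlap, so this count is no separate support. It also largely fixes the sign of the change inside batch 3, which compares some of the same samples. The median absolute change of the 101 genes was 0.933 log2 units pooled and 0.915 inside batch 3. The other largest rises were in Arl4d (1.63), Arrdc2 (1.56), Junb (1.35, 0.71 inside batch 3) and Ackr1 (1.19). The other largest falls were in the antisense transcript Gm15261 (−1.79), Slc13a1 (−1.57), Car4 (−1.46), Cep19 (−1.43), Zscan22 (−1.41, −0.94 inside batch 3), Gm28376 (−1.40), Gm15584 (−1.32), Gm44188 (−1.31) and Sox5os4 (−1.20). Gm15261, Gm28376, Gm15584 and Sox5os4 lie antisense to Arhgap6, Jph1, Brinp3 and Sox5, Junb overlaps Prdx2 and Ackr1 overlaps Cadm3, so which gene gave the reads is uncertain. Without CON 1, CON 2, CON 3 or TESS 3 the count was 59, 34, 46 or 18. With batch as a term edgeR called 0 genes, with 961 at unadjusted p under 0.05.

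Of the 28 lists tested in all nuclei, 10 passed with the preset correlation and none with an estimated one. The immediate early genes had a median of 1.10 over 21 of 34 measured members (adjusted p = 6.12e-13, but adjusted p = 0.181 with an estimated correlation; 0.559 inside batch 3). Of these, 8 rose and 0 fell over all genes, and 13 rose and 0 fell adjusted over the list alone. The glucocorticoid-response genes had a median of 0.88 over 15 of 17 (adjusted p = 2.22e-12, but adjusted p = 0.181 with an estimated correlation; 0.728 inside batch 3). Of these, 6 rose and 0 fell over all genes and 12 and 1 adjusted over the list alone. Reactive astrocyte genes followed with a median of 0.69 (adjusted p = 1.13e-05, and adjusted p = 0.181 with an estimated correlation). Lcn2, which binds bacterial iron carriers, rose 2.98 ± 0.49 and C4b, a complement component, rose 0.87 ± 0.14, while 4 members rose adjusted over the list alone. Blood and peripheral immune cell genes had a median of 0.58 (adjusted p = 3.52e-05, and adjusted p = 0.181 with an estimated correlation). The neutrophil genes S100a8 and S100a9 rose over all genes, while the haemoglobin genes Hbb-bs (0.75), Hba-a2 (0.83) and Hba-a1 (0.77) passed only adjusted over the list alone.

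The other lists that passed moved by smaller medians. Oxidative phosphorylation genes had a median of −0.22 (adjusted p = 3.74e-06, and adjusted p = 0.591 with an estimated correlation; −0.013 inside batch 3), with 0 members falling over all genes and 6 adjusted over the list alone. Cholesterol synthesis genes had a median of −0.11 (adjusted p = 0.00454, and adjusted p = 0.591 with an estimated correlation; −0.055 inside batch 3), where the enzyme genes Msmo1 (−0.94) and Fdft1 (−0.69) fell. Activated microglia genes had a median of 0.24 (adjusted p = 0.00637, and adjusted p = 0.591 with an estimated correlation), and Igf1, an insulin-like growth factor, rose 0.94 (0.39 inside batch 3). Voltage-gated channel genes had a median of 0.11 (adjusted p = 0.0222, and adjusted p = 0.591 with an estimated correlation) with no member passing over all genes. Delayed activity-response genes had a median of 0.19 (adjusted p = 0.0345, and adjusted p = 0.616 with an estimated correlation; 0.077 inside batch 3), and the prohormone convertase gene Pcsk1 rose 0.94. Myelinating oligodendrocyte genes had a median of −0.16 (adjusted p = 0.042, and adjusted p = 0.723 with an estimated correlation; 0.078 inside batch 3), and Opalin, a myelin membrane protein gene, fell by 0.89 (0.58 inside batch 3).

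The remaining 18 lists did not pass in all nuclei (adjusted p from 0.0945 to 0.979). Their medians were 0.38 for interferon-response, 0.09 for neuron, −0.19 for heat shock and chaperone, 0.08 for circadian clock, −0.06 for unfolded protein response, −0.12 for axon injury and regeneration, 0.07 for oligodendrocyte precursor, 0.14 for ependymal, −0.14 for pericyte and fibroblast, 0.44 for Schwann cell and 0.08 for endothelial genes. They were 0.11 for serotonin and dopamine receptor, −0.05 for GABA and glycine receptor, −0.06 for homeostatic microglia, −0.05 for ribosomal protein, 0.06 for homeostatic astrocyte and −0.06 for hypoxia and glycolysis genes, and 0.06 for glutamate receptor genes. The median, the mean and the test differed in sign for the serotonin and dopamine receptor, ribosomal protein, homeostatic astrocyte, and hypoxia and glycolysis lists. Single members of lists that did not pass still moved: Slc6a5 (0.78), Dnajb9 (−0.72), Sox10 (−0.83), Gal (−0.96) and Nts passed over all genes.

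The series set out to find the neurons recruited by TESS, so the main comparison was made in neurons. In neurons of TESS mice, 7 of 15 measured immediate early genes rose and the peptide genes Nts and Gal fell. As a list the immediate early genes lost their call with adjusted p = 0.58 with an estimated correlation. Per1 rose 1.67 ± 0.25 (adjusted p = 0.00258; chr11:69095217-69109960), from 14.6 ± 4.78 to 46.9 ± 11.6 CPM. It was called in each of the 6 fits that left out 1 sample. Egr1, a transcription factor gene induced by activity, rose 1.66 ± 0.34 (adjusted p = 0.0209; chr18:34859823-34864984), from 7.19 ± 3.38 to 22.1 ± 9.4 CPM. Fos rose 1.69 ± 0.37 (adjusted p = 0.0264), Nr4a3, an orphan nuclear receptor gene, rose 3.28 ± 0.59 (adjusted p = 0.0141), and Junb, a partner of Fos, rose 1.40 ± 0.31 (adjusted p = 0.0274). Nts fell by 1.23 ± 0.16 (adjusted p = 0.000641; chr10:102481756-102490486), from 214 ± 50.2 to 91.5 ± 13.8 CPM. Gal, the gene of the peptide galanin, fell by 0.95 ± 0.15 (adjusted p = 0.00466), from 130 ± 11.2 to 68.0 ± 12.6 CPM. With equal numbers of nuclei per subtype in every sample, chosen after seeing the data, the change was −0.59 for Nts and −0.42 for Gal, and Nts was no longer called, nor were Egr1 (1.36) and Junb (1.57). Within the subtype with the highest level, Nts changed by −0.51 ± 0.20 (adjusted p = 0.46) and Gal by −0.76 ± 0.21 (adjusted p = 0.0455).

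**Figure D1:**
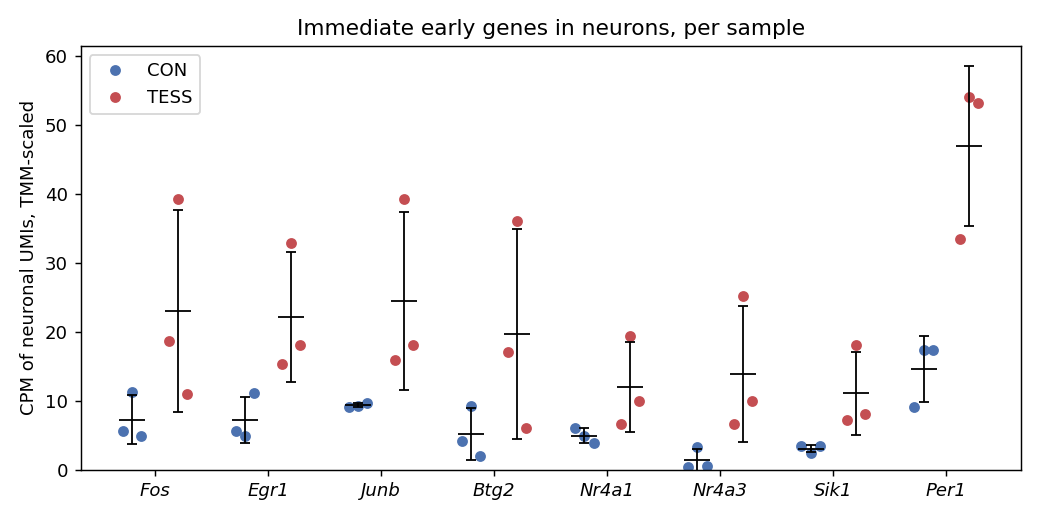
TMM-scaled CPM in neurons (vertical axis) of 8 immediate early genes in the 3 CON and 3 TESS samples; each point is a sample and each bar with whiskers the mean and SD. Per1 sits highest, with a mean of 14.6 in CON and 46.9 in TESS.

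Among 15 measured immediate early genes of 34, 12 were higher in TESS, with a median of 1.25 (adjusted p = 5.9e-09 with the preset correlation; 0.792 inside batch 3). The call was lost otherwise, with adjusted p = 0.58 with an estimated correlation and 0.173 by fry, and without TESS 2 the median was 0.682. Over all genes 7 members rose and 0 fell, and 9 rose and 0 fell adjusted over the list alone. Beside those above, Btg2 rose 1.97 ± 0.46 and Sik1, a salt-inducible kinase gene, rose 1.85 ± 0.42. Nr4a1 (1.25 ± 0.39, adjusted p = 0.123) and Gadd45g (0.74 ± 0.24, adjusted p = 0.138) passed only adjusted over the list alone. These genes rest on few molecules: the 3 CON and 3 TESS samples held 53 and 106 UMIs of Fos in neurons, 67 and 108 of Junb, 50 and 97 of Egr1, 36 and 52 of Nr4a1, and 10 and 61 of Nr4a3. Inside batch 3 the change was 1.35 for Per1, 1.54 for Egr1, 0.79 for Junb, 1.87 for Nr4a3 and 0.27 for Nr4a1. Fosb (0.41 CPM in CON and 3.64 in TESS, 3 and 16 UMIs), Arc (2.86 and 4.32 CPM, 21 and 19 UMIs) and Npas4 (2.59 and 3.41 CPM, 19 and 15 UMIs) were too low to test. So was Drd1, the D1 receptor gene (3.82 and 2.50 CPM, 28 and 11 UMIs). Htr1a, the 5-HT1a receptor gene (5.59 and 3.87 CPM, 41 and 17 UMIs), did not pass (−0.56 ± 0.45, adjusted p = 0.606).

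Beyond the immediate early genes, the largest rises in neurons were in Abca1, a cholesterol exporter gene (1.62 ± 0.33), Ackr1, an atypical chemokine receptor gene that overlaps Cadm3 (1.16), Bcl6, a transcriptional repressor gene (1.05), Tpm4, a tropomyosin gene (1.04), Tiparp, an ADP-ribosyltransferase gene (1.03), Ell2, an elongation factor gene (1.03), and Pcsk1 (0.94 ± 0.17). Pcsk1 and Tiparp belong to the delayed activity-response list, which did not pass (median 0.26 over 18 of 22, adjusted p = 0.0978; 2 rose and 0 fell, 4 and 1 adjusted over the list alone). The largest falls were in Gm15261 (−1.85 ± 0.20, adjusted p = 4.45e-05; chrX:169037674-169106536), from 94.5 ± 16.1 to 25.1 ± 8.77 CPM, and in Amelx (−1.78). Both lie opposite Arhgap6, so the source of their reads is uncertain. They were followed by Cep19, a centrosomal protein gene (−1.47 ± 0.23, adjusted p = 0.00409), Gm4128 (−1.34), Gm15584 (−1.30), Gm44188 (−1.28), Zscan22 (−1.24), the kinesin gene Kif24 (−1.20) and Sox5os4 (−1.16). Msmo1 (−0.99 ± 0.19) and Dnajb9, an endoplasmic reticulum co-chaperone gene (−0.73), fell. Slc6a5, the glycine transporter of glycinergic terminals, rose 0.78 ± 0.15, from 160 ± 10.5 to 274 ± 79.5 CPM. Inside batch 3 Tpm4 stood at 0.69, Tiparp at 0.49, Zscan22 at −0.73 and Msmo1 at −0.48.

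Of 11,686 genes tested in neurons, 32 rose and 90 fell. The groups did not overlap in 119 of these 122 genes, against 19.9% of all genes tested and 10% by chance, and the median absolute change was 0.781 pooled and 0.736 inside batch 3. DESeq2 called 109 genes, 74 of them shared. The count was 25, 33 or 19 without CON 2, CON 3 or TESS 3, and 6 genes were called in every fit that left out a sample. With batch as a term edgeR called 0 genes, with 765 at unadjusted p under 0.05. Of 26 lists tested, the glucocorticoid-response genes (median 0.38 over 12 of 17, adjusted p = 0.00597, and adjusted p = 0.546 with an estimated correlation) and the oxidative phosphorylation genes (−0.13, adjusted p = 0.0088, and adjusted p = 0.72 with an estimated correlation; 0.094 inside batch 3) also passed. In the former only Per1 rose over all genes, and no member of the latter passed over all genes. The axon injury and regeneration list, which holds Nts and Gal, did not pass (−0.09, adjusted p = 0.184; 0 rose and 2 fell, 2 and 4 adjusted over the list alone). The serotonin and dopamine receptor list did not pass either (adjusted p = 0.446). The median, mean and test differed in sign for the latter and for the oligodendrocyte precursor, interferon-response, ribosomal protein and homeostatic astrocyte lists.

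Excitatory and inhibitory neurons were then compared separately. In excitatory neurons Egr1 rose 1.98 ± 0.42 (adjusted p = 0.0117), Per1 rose 1.59 ± 0.27 (adjusted p = 0.00238) and Junb rose 1.40 ± 0.35, together with Pcsk1 (0.91) and Peg3, an imprinted zinc finger gene (0.87 ± 0.17), which went from 103 ± 25.6 to 188 ± 22.8 CPM. Nts fell by 1.22 ± 0.16 (adjusted p = 2.89e-05). In inhibitory neurons Fos rose 2.37 ± 0.48 (adjusted p = 0.0167), from 4.93 to 25.9 CPM. There Per1 rose 1.75 ± 0.34 and Slc6a5 rose 0.80 ± 0.17, from 334 to 578 CPM. Gal fell by 1.32 ± 0.19 in inhibitory neurons (adjusted p = 0.000368; chr19:3409915-3414544), from 277 ± 13 to 113 ± 38.9 CPM, and so did the peptide genes Cartpt (1.31 ± 0.27) and Npy (0.87 ± 0.17).

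Of 10,364 genes tested in excitatory neurons, 20 rose and 68 fell. The other named rises were in Ackr1 (1.30), Tiparp (1.13, 0.55 inside batch 3), the tau kinase gene Ttbk1 (1.02 ± 0.20), Ell2 (0.90) and Gm26917 (0.80, 0.219 inside batch 3). The named falls were in Gm4128 (−1.88), Gm15261 (−1.79), Amelx (−1.66), Gm14582 (−1.64) and A630012P03Rik (−1.61), both antisense to Gpc3, Gm15584 (−1.61), Dgat2, which makes triglycerides (−1.51), Cep19 (−1.42), Slc35a5 (−1.39) and Sox5os2 (−1.35). All 88 had groups that did not overlap, against 17.8% of genes tested and 10% by chance. Of 25 lists, 5 passed with the preset correlation and none with an estimated one: immediate early genes (1.17 over 7, adjusted p = 7.35e-05; 3 rose, 5 adjusted over the list alone), glucocorticoid-response genes (0.27, adjusted p = 0.0184), oxidative phosphorylation genes (−0.14, 0.111 inside batch 3, adjusted p = 0.00736), unfolded protein response genes (−0.20, −0.08 inside batch 3, adjusted p = 0.0355) and heat shock genes (−0.33, −0.054 inside batch 3, adjusted p = 0.0355). The first pair had adjusted p = 0.402 with an estimated correlation, and the last 3 had adjusted p = 0.58 with an estimated correlation. No member of the last 3 lists passed over all genes; adjusted over the list alone, Cryab and Hsp90ab1 fell among the heat shock genes. The count was 55, 50 or 34 without CON 2, CON 3 or TESS 3, and DESeq2 called 44. With a batch term it was 24, of which 18 were among the 88.

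Of 9069 genes tested in inhibitory neurons, 8 rose and 21 fell, and 28 of these 29 had groups that did not overlap, against 16.5% of genes tested and 10% by chance. The other rises were in Abca1 (2.19), Ell2 (1.16), the zinc finger gene Tshz3 (0.94), Rgs7bp (0.72, 0.46 inside batch 3) and the kinesin gene Kif5c (0.68). The other named falls were in Gm15261 (−2.05), Cep19 (−1.50), 4930545L23Rik, antisense to Plcb1 (−1.36), Zscan22 (−1.34), Mycbp (−1.17), Gm12064, antisense to Bcl11a (−1.17), Dnajb9 (−0.98) and Msmo1 (−0.97, −0.45 inside batch 3). Npy stood at −0.52 inside batch 3. Cholesterol synthesis genes passed (−0.42 over 13, −0.273 inside batch 3, adjusted p = 0.00376, and adjusted p = 0.622 with an estimated correlation): Msmo1 fell over all genes, and Fdft1, Sqle, Sc5d and Cyp51 fell too adjusted over the list alone. Immediate early genes (0.78 over 6, adjusted p = 0.00462; 2 rose, 3 adjusted over the list alone), glucocorticoid-response genes (0.39, adjusted p = 0.0101) and delayed activity-response genes (0.37, 0.22 inside batch 3, adjusted p = 0.0486; 0 rose, 5 adjusted over the list alone) also passed, each with adjusted p = 0.622 with an estimated correlation. So did the oxidative phosphorylation genes (−0.18, 0.059 inside batch 3, adjusted p = 0.0268; adjusted p = 0.842 with an estimated correlation). The count was 49, 14 or 2 without CON 1, CON 2 or TESS 3, and DESeq2 called 11. With a batch term it was 3, of which 2 were among the 29.

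Which neuron subtypes carried the immediate early gene response was asked with the summed level of the 34 listed genes in 24 subtypes. It was higher in TESS in 23 of 24 subtypes, and 3 passed: the inhibitory ventral subtype V1/V2b/Stmn3 (1.66 ± 0.33 log2 units, adjusted p = 0.026, from 31 to 85 UMIs), the excitatory subtype Pdyn (1.88 ± 0.45, adjusted p = 0.0382) and the excitatory subtype Crh (1.5 ± 0.40, adjusted p = 0.0474). The next largest differences, in V1/V2b/Tenm2 (1.32 ± 0.44, adjusted p = 0.08) and Fxyd6 (1.11 ± 0.40, adjusted p = 0.0843), did not pass. The smallest were in Rorb (0.22), Pnoc (0.04) and Npy (−0.74 ± 1.11). The Npy value rests on 8 UMIs in each group, and its mean level ran the other way, with 108.2 CPM in CON and 136.2 CPM in TESS (SD 35.5 and 165.5). Unadjusted p was under 0.05 in 12 subtypes. Without CON 1, CON 2, CON 3 or TESS 3 limma called 0 subtypes, with 7, 6, 5 or 8 at unadjusted p under 0.05, and without TESS 1 it called 16, of which 15 were higher. The call also ended when the level was TMM-normalized (0 subtypes, 4 at unadjusted p under 0.05) or when the replicate number was a block (0 subtypes, 8 at unadjusted p under 0.05).

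**Figure D2:**
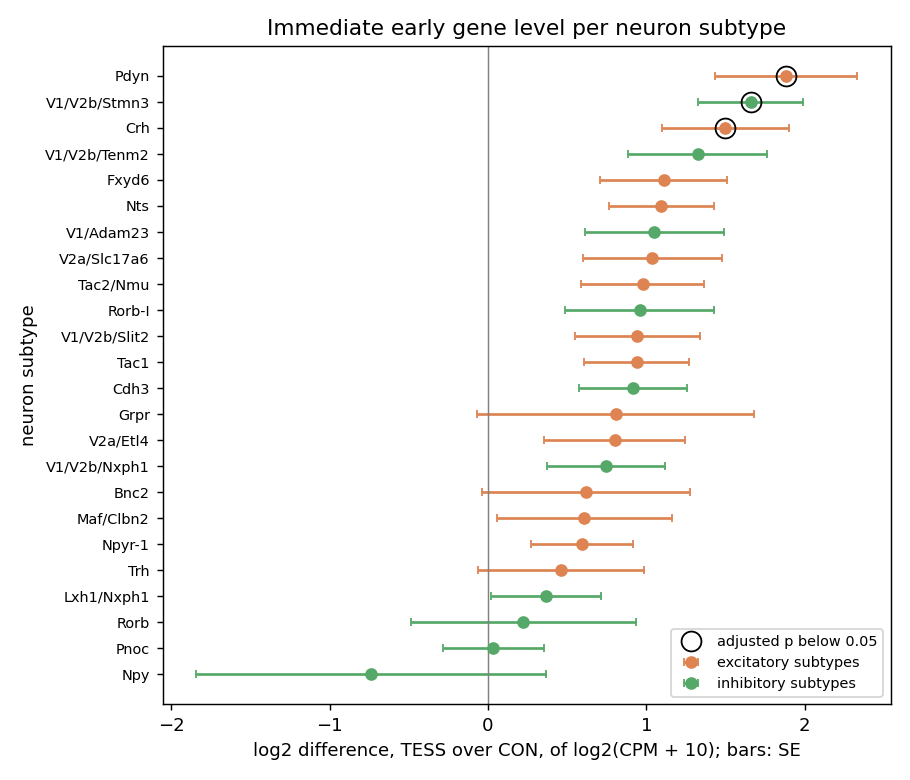
Difference between TESS and CON in the immediate early gene level (horizontal axis, log2 of CPM plus 10) for 24 neuron subtypes; points are estimates from 3 against 3 samples, bars their SE, colours mark excitatory and inhibitory subtypes and circles an adjusted p below 0.05. The circled subtypes are Pdyn (1.88), V1/V2b/Stmn3 (1.66) and Crh (1.5).

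Gene by gene, the neuron subtypes gave 26 calls in 11 of 24 subtypes over 31,412 tests, 5 higher and 21 lower in TESS. The p-values were adjusted within each subtype and not across the 24 subtypes. In the excitatory subtype Fxyd6 the peptide gene Nms fell by 2.14 ± 0.40 (adjusted p = 0.00174), and in the subtype Pdyn the opioid peptide gene Penk fell by 1.07 and the potassium channel subunit gene Kcnab1 rose 1.53. In the inhibitory subtype Pnoc, Gal fell by 0.76 and Malat1, a nuclear non-coding RNA, fell by 0.80, with 4930555F03Rik (−1.65). In Grpr, Strbp (−1.34), Gm15398 (−1.56) and Nrg3os (−1.36) fell, and in Maf/Clbn2 Tshz3 rose 1.39 while Gm20642 (−1.27) and Gm11418 (−1.80) fell. The count was 61 or 13 without CON 1 or CON 2, and DESeq2 called 8.

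The series text does not name a question for the other cell types. In oligodendrocytes, which make myelin, 6 of 14 measured genes induced by glucocorticoid hormone rose. As a list they lost their call with adjusted p = 0.206 with an estimated correlation. Nfkbia rose 2.62 ± 0.30 (adjusted p = 5.47e-05; 3.05 inside batch 3; chr12:55489410-55492647), from 15.0 ± 4.69 to 87.6 ± 32.9 CPM. Fkbp5 rose 2.05 ± 0.38 (adjusted p = 0.00422; chr17:28399094-28517527), from 34.2 ± 14.5 to 140 ± 109 CPM, and Sgk1, a kinase gene induced by glucocorticoids, rose 1.60 ± 0.25 (adjusted p = 0.00108), from 259 ± 131 to 777 ± 99.1 CPM. Ddit4, an inhibitor of mTOR signalling (1.53 ± 0.24), Errfi1, an inhibitor of EGF receptor signalling (1.19 ± 0.20), and the transcription factor gene Klf9 (0.77 ± 0.19) rose too. Opalin (−0.87 ± 0.18), Ugt8a, which makes myelin galactolipids (−0.65 ± 0.14), and Sox10, the master regulator of the lineage (−0.89, from 645 to 350 CPM), fell.

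**Figure D3:**
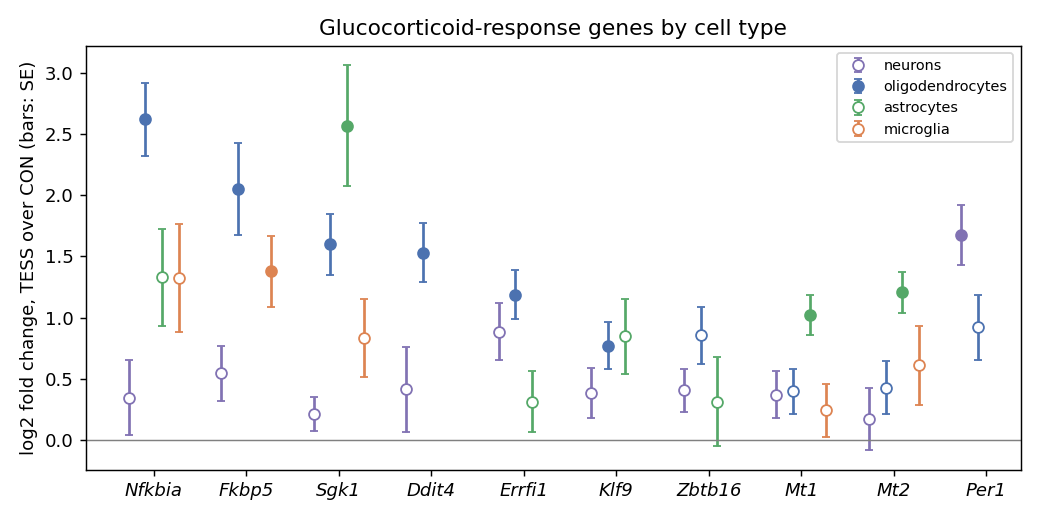
Log2 fold change of TESS over CON with its SE (3 against 3 samples) for 10 glucocorticoid-response genes in neurons, oligodendrocytes, astrocytes and microglia; filled points have an adjusted p below 0.05. Filled in oligodendrocytes are Nfkbia (2.62), Fkbp5 (2.05), Sgk1 (1.60), Ddit4 (1.53), Errfi1 (1.19) and Klf9 (0.77).

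The glucocorticoid-response list had a median of 1.05 over 14 of 17 members in oligodendrocytes (adjusted p = 1.58e-13, and adjusted p = 0.206 with an estimated correlation; 1.10 inside batch 3), with 6 rising and 0 falling over all genes and 10 and 0 adjusted over the list alone. Ion channel and receptor genes usually counted as neuronal were higher as well. Voltage-gated channel genes had a median of 0.53 over 25 of 33 (adjusted p = 9.51e-10, and adjusted p = 0.541 with an estimated correlation). The potassium channel genes Kcnma1 (1.55 ± 0.22, 0.87 inside batch 3), Kcna2 (1.25 ± 0.30) and Kcnd2 (1.03 ± 0.22) rose, 7 members adjusted over the list alone. Glutamate receptor genes had a median of 0.62 over 19 of 23 (adjusted p = 0.000117, and adjusted p = 0.541 with an estimated correlation; 0.374 inside batch 3). Gria3 (1.29) and Grm5 (1.06) rose over all genes, and 3 rose and 1 fell adjusted over the list alone. The GABA receptor gene Gabrg3 rose 1.48 in a list that did not pass (adjusted p = 0.0797). Beside these stands a measured fact: genes at least 10 times higher in neurons than in oligodendrocytes took 0.847%, 0.902% and 1.16% of oligodendrocyte UMIs in CON 1, CON 2 and CON 3 and 1.41%, 1.52% and 2.63% in TESS 1, TESS 2 and TESS 3.

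**Figure D4:**
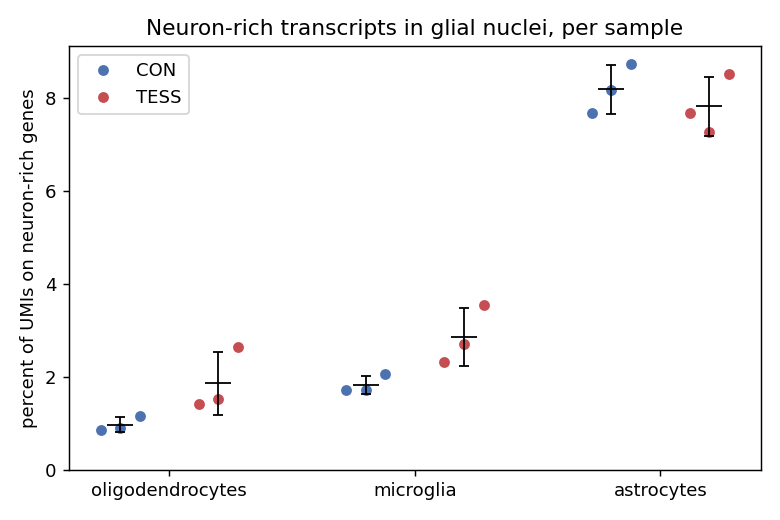
Percent of the UMIs of oligodendrocytes, microglia and astrocytes (vertical axis) that fall on genes at least 10 times higher in neurons than in oligodendrocytes, one point per sample with the group mean and SD. In oligodendrocytes the CON samples lie between 0.847 and 1.16 and the TESS samples between 1.41 and 2.63, while in astrocytes the groups overlap. The same genes are used for each type, so in astrocytes they were not chosen against the level in astrocytes. The 24 tested genes 10 times higher in neurons than in astrocytes had a median log2 fold change of 0.719 in astrocytes.

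Oxidative phosphorylation genes had a median of −0.35 in oligodendrocytes (adjusted p = 1.34e-07, and adjusted p = 0.541 with an estimated correlation; −0.023 inside batch 3), where Ndufa4 (−0.84), Atp5g1 (−0.79) and Cox6a1 (−0.65) fell, 6 members adjusted over the list alone. Inside batch 3 these genes stood at −0.51, −0.36 and −0.42 (Ndufa4, Atp5g1 and Cox6a1). Reactive astrocyte genes had a median of 0.63 over 6 of 21 (adjusted p = 0.000841, and adjusted p = 0.206 with an estimated correlation). The members that rose, C4b (0.86 ± 0.15) and the protease inhibitor gene Serpina3n (0.96 ± 0.21), encode secreted proteins of the acute phase. Smaller shifts passed for cholesterol synthesis (−0.27, adjusted p = 0.0303; adjusted p = 0.607 with an estimated correlation; Msmo1 fell by 0.79), homeostatic astrocyte (0.24, adjusted p = 0.0377; adjusted p = 0.607 with an estimated correlation), heat shock (−0.27, 0.124 inside batch 3, adjusted p = 0.0377; adjusted p = 0.629 with an estimated correlation) and myelinating oligodendrocyte genes (−0.16, −0.047 inside batch 3, adjusted p = 0.0377; adjusted p = 0.644 with an estimated correlation). Immediate early genes did not pass here (median −0.06 and mean 0.215 over 5 of 34, adjusted p = 0.404). Most were too low to test. Over the summed CON and TESS samples Fos stood at 7.96 and 16.8 CPM (22 and 27 UMIs) and Junb at 6.51 and 18.1 CPM (18 and 29 UMIs). Fosb and Arc had a lower CPM in TESS.

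Of 8796 genes tested in oligodendrocytes, 94 rose and 51 fell, and in 143 of these 145 the groups did not overlap, against 19.7% of genes tested and 10% by chance. Further named rises were in Megf6 (2.00), Gli2 (1.97), Zmat4 (1.88), Hif3a (1.85), Rnf125 (1.80), Arl4d (1.74), Arrdc2 (1.69) and the glycosyltransferase gene Wbscr17 (1.63). Named falls were in Zscan22 (−1.94), Tac2 (−1.86), Zfp866 (−1.81), Serpine3 (−1.72), Slc13a1 (−1.59), Far1os (−1.56), Gm28376 (−1.43 ± 0.20), Snrnp27 (−1.42), Mocs2 (−1.27) and Gm29417 (−1.19). Gm28376, Far1os and Gm29417 are antisense to Jph1, Far1 and Cxxc5, and Serpine3 and Zfp866 overlap other genes, so the source of their reads is uncertain. The count was 81, 38 or 32 without CON 1, CON 2 or TESS 3. With a batch term it was 73, of which 49 were among the 145. Without genes 2 times higher in neurons edgeR called 70 genes, 35 higher and 35 lower; 84 of the 145 were still tested and 69 of them called.

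In astrocytes, which buffer ions and transmitter in the cord, the same hormone-induced group was higher. Sgk1 rose 2.57 ± 0.49 (adjusted p = 0.00126), and the metallothionein genes Mt2, from 1535 to 3558 CPM, and Mt1, from 2624 to 5325 CPM, rose 1.21 ± 0.17 and 1.02 ± 0.16. Gfap, the filament gene of reactive astrocytes, rose 1.11 ± 0.22 (adjusted p = 0.0018), from 551 to 1188 CPM (0.72 inside batch 3). The glucocorticoid-response list had a median of 0.93 over 8 of 17 (adjusted p = 6.12e-11; 0.806 inside batch 3), 3 members rose over all genes and 6 adjusted over the list alone, and adjusted p was 0.0239 with an estimated correlation. It was the only list call in any class that held with an estimated correlation. Oxidative phosphorylation genes (−0.26, −0.128 inside batch 3, adjusted p = 0.00322; adjusted p = 0.261 with an estimated correlation; Ndufa4 fell by 1.06), myelinating oligodendrocyte genes (0.26, 0.613 inside batch 3, adjusted p = 0.0287; adjusted p = 0.68 with an estimated correlation) and homeostatic astrocyte genes (0.11, 0.188 inside batch 3, adjusted p = 0.0482; adjusted p = 0.68 with an estimated correlation) also passed. In the last, Agt, the angiotensin precursor gene, rose 0.62. Of 2049 genes tested, 16 rose and 4 fell, 17 of them with groups that did not overlap against 16.5% of genes tested and 10% by chance. The other named genes were Nrg1 (1.71), Cntnap2 (1.55), Slc24a4 (1.40, 0.92 inside batch 3), Rhou (1.39), Lrrtm4 (1.24), Ccser1 (1.23), Gm42649 (−1.95), 9630028H03Rik, antisense to Plcb1 (−1.45, −0.86 inside batch 3), and Wdr17 (−1.31), with Gm26704 (−1.63, adjusted p = 0.055) not passing. The 24 tested genes at least 10 times higher in neurons than in astrocytes had a median change of 0.719. The count was 9 or 8 without CON 3 or TESS 3, DESeq2 called 6 and a batch term left 3. Without genes 2 times higher in neurons it was 14, each among the 20.

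In microglia, the resident immune cells, the chemokine gene Ccl4 fell by 1.91 ± 0.36 (adjusted p = 0.0106), from 737 ± 294 to 179 ± 111 CPM, and Fkbp5 rose 1.38 ± 0.29 (adjusted p = 0.0186). The other named rises were in Lrrc7 (2.37), Opcml (2.19 ± 0.35), Tenm2 (2.11), Fam155a (1.89), Lrrc4c (1.48), Il1rapl1 (1.40), Lrrtm4 (1.40), the nuclear receptor gene Rora (1.38) and Nrg3 (1.31). The neuron gene list did not pass (median 0.11 over 8 of 21, adjusted p = 0.732). Genes at least 10 times higher in neurons than in oligodendrocytes took 1.72%, 1.71% and 2.05% of microglial UMIs in the CON samples and 2.31%, 2.70% and 3.54% in the TESS samples. The 49 tested genes at least 10 times higher in neurons than in microglia had a median change of 1.114. Arhgap5 (−1.12), the ubiquitin gene Ubb (−1.09) and Csmd3 (−1.03, −0.57 inside batch 3) fell, and Nr6a1 (−1.14, adjusted p = 0.075) did not pass. Homeostatic microglia genes had a median of −0.46 (adjusted p = 1.18e-05, and adjusted p = 0.488 with an estimated correlation; −0.143 inside batch 3). Over all genes 0 fell, and Cx3cr1 (−0.78) and P2ry12 (−0.69), the fractalkine and ADP receptors, fell adjusted over the list alone. Oxidative phosphorylation (−0.37, −0.037 inside batch 3, adjusted p = 1.18e-05; adjusted p = 0.488 with an estimated correlation), glutamate receptor (0.80, adjusted p = 3.08e-05; adjusted p = 0.394 with an estimated correlation; 4 rose adjusted over the list alone), voltage-gated channel (0.66, adjusted p = 0.0309; adjusted p = 0.488 with an estimated correlation) and glucocorticoid-response genes (0.61, 0.045 inside batch 3, adjusted p = 0.0309; adjusted p = 0.394 with an estimated correlation) passed as well. Of 2501 genes tested, 11 rose and 4 fell, each with groups that did not overlap, against 17.4% of genes tested and 10% by chance. The count was 7, 1, 34, 48 or 1 without CON 1, CON 2, CON 3, TESS 1 or TESS 3. With a batch term it was 8, of which 5 were among the 15, and without genes 2 times higher in neurons it was 3, each among the 15.

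Oligodendrocyte precursor cells and endothelial cells were the thinnest types tested. In the precursors Cntnap2, an adhesion gene of neurons, rose 1.98 ± 0.29 (adjusted p = 0.000268) and Mertk, a phagocytic receptor gene, rose 1.70 ± 0.36 (adjusted p = 0.0428), the only calls among 1289 genes. Myelinating oligodendrocyte genes had a median of −0.46 over 9 (adjusted p = 0.00602, and adjusted p = 0.502 with an estimated correlation; −0.829 inside batch 3). Nell2 (1.54), Apod (1.14), Rap1gap (1.28), Sec11c (−1.40), Sec62 (−1.13), Gm26916 (−1.24), Sema4d (−1.58) and Prdx1 (−1.28) did not pass (adjusted p from 0.0649 to 0.267). In endothelial cells, with 25 to 62 nuclei per sample, Btg2 rose 2.37 ± 0.41 (adjusted p = 0.0168), from 197 ± 30.1 to 1106 ± 355 CPM, and Apold1, an immediate early gene of vessels, rose 2.22 ± 0.39. The ceramidase gene Acer2 (1.91), Mt2 (1.53) and Col4a3bp (1.08) rose, and Ptn, a growth factor gene (−1.37 ± 0.19), Car4, a carbonic anhydrase of capillaries (−1.54, −1.02 inside batch 3), Malat1 (−0.95) and Actb (−0.91) fell, among 583 genes tested; Ubb (−1.11, adjusted p = 0.0596) did not pass. Oxidative phosphorylation (−0.45), pericyte and fibroblast (−0.80) and ribosomal protein genes (−0.20) passed in endothelial cells at adjusted p = 0.028 each, with adjusted p = 0.245, 0.245 and 0.447 with an estimated correlation. The precursor count was 14, 7 or 6 without CON 1, CON 3 or TESS 3, and 0 without genes 2 times higher in neurons, with 106 at unadjusted p under 0.05 in edgeR. The endothelial count was 2 without CON 1 or TESS 3 and 0 without CON 3, TESS 1 or TESS 2 (97, 92 and 97 at unadjusted p under 0.05), DESeq2 called 2, and a batch term left 0 (29 at unadjusted p under 0.05).

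In the classes other than all nuclei and all neurons, the lists whose median, mean and test differed in sign did not pass. They were the cholesterol synthesis, homeostatic astrocyte, activated microglia and ribosomal protein genes in excitatory neurons. In inhibitory neurons they were the neuron, axon injury and regeneration, GABA and glycine receptor, interferon-response and activated microglia genes. In oligodendrocytes they were the immediate early, hypoxia and glycolysis, and axon injury and regeneration genes. The others were the glutamate receptor genes in astrocytes and precursors, and the ribosomal protein genes in microglia.

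Whether the response differed between classes was tested directly. Between neurons and all other nuclei, 11 of 12,577 genes differed, all with the lower change in neurons: Fkbp5 changed by 0.55 in neurons and 1.99 in other nuclei (difference −1.49 ± 0.22, adjusted p = 0.000723), and Sgk1 by 0.22 and 1.51 (difference −1.38, adjusted p = 0.00449). None of the 11 genes is a listed immediate early gene. Over summed CON and TESS samples Fos stood at 7.23 and 24.1 CPM in neurons and 7.85 and 21.3 CPM in other nuclei. In other nuclei Egr1 stood at 6.63 and 25.0 CPM and Junb at 13.7 and 33.8 CPM, while Arc was lower in TESS (11.5 and 10.0 CPM). Between excitatory and inhibitory neurons 8 of 10,559 genes differed, among them 3 peptide genes with the lower change in inhibitory neurons: Cartpt (0.30 and −1.31, difference 1.60 ± 0.27, adjusted p = 0.000129), Gal (0.06 and −1.32, difference 1.45) and Npy (0.11 and −0.87, difference 1.00). The first count was 6, 5, 33 or 0 without CON 1, CON 2, TESS 1 or TESS 2 (838 at unadjusted p under 0.05 in edgeR for the last) and 4 with limma. The second was 3, 5, 4 or 3 without CON 2, CON 3, TESS 1 or TESS 3 and 0 with limma (575 at unadjusted p under 0.05).

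Cell type shares were compared to ask whether TESS samples held other proportions of cells. Neurons made up 32.5 ± 0.41% of nuclei in CON and 32.6 ± 4.98% in TESS, oligodendrocytes 48.6 ± 2.57% and 46.6 ± 5.10%, microglia 8.31 ± 1.24% and 9.83 ± 2.23%, and astrocytes 6.13 ± 2.15% and 5.55 ± 1.82%. Precursors made up 3.29 ± 0.86% and 4.24 ± 1.26%, and endothelial cells 1.18 ± 0.45% and 1.19 ± 0.21%. The exact permutation p was 0.4 to 1 for the 6 types, where 0.1 is the smallest possible, and edgeR called 0 types (smallest unadjusted p = 0.228). Among the 38 neuron subtypes edgeR called 0 shares (7 at unadjusted p under 0.05, smallest adjusted p = 0.271); V2a/Etl4 (0.67 ± 0.24) and Tac1 (−0.47 ± 0.18) were among those 7.

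Ranking subtypes by how well their nuclei reveal the treatment is the purpose the series title names. The mean AUC over 11 subtypes was 0.542 ± 0.033 (SD over 9 held-out pairs). The highest values were those of Tac1 (0.656 ± 0.075), V1/V2b/Tenm2 (0.606 ± 0.051), Fxyd6 (0.582), V2a/Slc17a6 (0.561) and Lxh1/Nxph1 (0.546). The lowest were those of V1/Adam23 (0.477), Cdh3 (0.471) and Npyr-1 (0.448). The 9 pairs share samples. Simulated nuclei with no difference, at depths in the ratio of the samples' medians, gave 0.558 ± 0.0523 (SD over 10 simulations), above the mean and above Lxh1/Nxph1. They lacked the real UMI totals and the spread between samples, so 0.558 is only a rough reference. In Lxh1/Nxph1 4 of the 10 splits of the samples were as high, the highest at 0.6694. With nuclei thinned to 500 UMIs the mean was 0.512 and the order changed, with Npyr-1 at 0.571, V1/Adam23 at 0.569, Tac1 at 0.533 and V1/V2b/Tenm2 at 0.465. Without CON 1, CON 2 or CON 3 the mean fell below 0.5, to 0.465, 0.458 or 0.467.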

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

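The test of gene length over all genes of oligodendrocytes, the equal subtype composition, the use of other sample splits for the immediate early gene list, the test of UMIs per nucleus of glucocorticoid-response genes, and the choice of neuropeptide genes as a group came only after the results were seen; the remaining tests here were set beforehand. For the patterns of gene groups described below, ± is the SD over 1000 bootstrap draws of genes, with the samples held fixed. It leaves out the spread between samples, so what is argued against there is argued against for these samples only. The interaction tests singled out the genes below because their TESS effect differed between cell classes.

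Between neurons and other nuclei the log2 effect in neurons minus that in other nuclei was −1.49 for Fkbp5 (adjusted p = 0.000723) and −1.38 for Sgk1 (adjusted p = 0.00449), both genes induced by glucocorticoids. It was −1.41 for Wbscr17 (adjusted p = 0.000703), which was called higher in oligodendrocytes. The aminopeptidase gene Rnpep differed by −1.43, with changes of −0.28 in neurons and 1.11 in other nuclei. The integrin gene Itga5 differed by −1.83 (−0.52 and 1.24), and Ptgfrn, a membrane protein gene, by −1.64 (−0.52 and 1.09). Nrg1, which encodes neuregulin, differed by −1.20 (0.16 and 1.36), and Cntnap2 by −1.20 (0.09 and 1.30). Galntl6 differed by −1.25, Gm28928 by −1.37 and Dtnbos by −1.02, all at adjusted p = 0.0373.

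Between excitatory and inhibitory neurons the effect in excitatory minus that in inhibitory neurons was 1.60 for Cartpt, 1.45 for Gal and 1.00 for Npy, all peptide genes. The muscarinic receptor gene Chrm3 differed by 0.614, with changes of 0.20 and −0.43, and the kainate receptor gene Grik2 by 0.383 (0.28 and −0.10). The synaptic adhesion gene Nrxn3 differed by 0.285 (0.40 and 0.13) and the glypican gene Gpc5 by 0.389 (0.21 and −0.19). Dgat2 differed the other way, by −2.13, with changes of −1.51 in excitatory and 0.60 in inhibitory neurons (adjusted p = 0.011).

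The first pattern is that transcripts of neurons, mainly of long genes, were higher in oligodendrocytes of TESS samples. Of 255 genes at least 10 times higher in neurons than in oligodendrocytes, 92.2% had a change above 0. Their median was 0.785, and 45 rose while 1 fell. The median was 0.907 for the 181 of them over 200 kb and 0.017 for the 21 under 50 kb. In neurons the same long and short genes had medians of 0.037 and −0.298. Of the fixed neuron gene list, no member passed in oligodendrocytes over all genes. Syt1 (0.99) and Rbfox1 (0.80) passed adjusted over the list alone. Free RNA that held long and short genes as neuronal nuclei do would shift both alike beyond their change in neurons. The oligodendrocyte change minus the neuron change was instead larger for long genes, by 0.508 ± 0.146 (181 over 200 kb, 21 under 50 kb). This argues against free RNA of that make-up only, and free RNA of another make-up stays open. Genes 10 times higher in neurons than in the type itself also had medians of 1.114 in microglia and 0.719 in astrocytes. A length effect on all oligodendrocyte genes is also argued against, since among genes that are not neuronal the long ones exceeded the short ones by only 0.111 ± 0.012. A length difference within neurons, 0.15 ± 0.009, did not decide whether intronic reads take part. The batch cannot be told apart from the group, because batch 3 holds 1 TESS library: the median inside it was 0.783 ± 0.045 times the pooled one, and expression of these genes by oligodendrocytes after stimulation, which may also give the pattern, was not tested.

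The second pattern is that glucocorticoid-response genes were higher in oligodendrocytes of TESS samples, where 6 of 14 rose and the list lost its call with adjusted p = 0.206 with an estimated correlation. Time of day is argued against only by the 6 measured of 9 listed clock output genes, which shift with the hour. Their absolute median change was 0.087 ± 0.112, against 1.05 for the glucocorticoid-response list, and the median of their absolute changes was 0.101. The largest was 0.511 for Ciart (edgeR adjusted p = 0.627). Per1, a clock gene outside this set and itself a member of the glucocorticoid-response list, changed by 0.92 in oligodendrocytes and passed only adjusted over the list alone. The set was examined in oligodendrocytes only. In neurons Cry2, another clock gene outside it, changed by 0.64 and passed only adjusted over the circadian clock list alone. The batch stays open, since the median in oligodendrocytes inside batch 3 was 1.04 ± 0.19 times the pooled one but rests on 1 TESS library, and in microglia the median was 0.045 inside batch 3 against 0.608 pooled. Free RNA shared by all nuclei was left open by the fraction of members called in oligodendrocytes with a 2 times higher level in another cell type, 0.5, but is argued against as the whole cause: it would add as many UMIs to each nucleus, whereas beyond the CON level oligodendrocytes of TESS samples held more UMIs per nucleus than neurons, by a median of 0.019 ± 0.005 over 14 members. A candidate explanation tied to the design, a stress hormone response to stimulation and stepping, was not tested.

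The third pattern rests on a group put together after falls had been seen and not tested for enrichment: of 20 measured neuropeptide genes, 19 had a change below 0 in neurons, 7 fell and 0 rose, and the median was −0.654. A lower number of nuclei from peptide-rich subtypes is argued against as the whole cause, since the median was −0.418 ± 0.102 with equal subtype composition, although Nts went from −1.23 to −0.59 and Gal from −0.95 to −0.42. Free RNA in neurons was not decided by the median in the subtype with the highest level of each gene, −0.448 ± 0.164. The batch stays open, with a median inside batch 3 that was 0.736 ± 0.262 times the pooled one and rests on 1 TESS library. Use of peptide messenger during activity may also lower such transcripts, which was not tested.

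The 6 samples can be split into 3 and 3 in only 10 ways, too few for a share of splits under 0.05. The real split gave 122 genes in neurons, 101 in all nuclei, 145 in oligodendrocytes and 15 in microglia, where the highest other split gave 0 in each. It gave 88 in excitatory neurons, 29 in inhibitory neurons and 20 in astrocytes, where the highest other gave 1 in each. For the subtype tests the numbers were 26 and 11, for neurons against other nuclei 11 and 3, for excitatory against inhibitory neurons 8 and 4, for the subtypes past the threshold for the immediate early gene level 3 and 0, and for the median of the immediate early genes in neurons 1.253 and 0.752. In each of these 1 split, the real one, gave as large a result. In endothelial cells 2 splits gave at least the real 9 genes, the highest other giving 11, and in precursors 3 splits gave at least the real 2 genes, the highest other giving 11 and the split that follows batch 3 giving 2. The mean AUC was 0.5421 against 0.548 for the highest other split, which is the one that follows batch 3, so 2 splits were as large. For subtype shares all 10 splits gave 0 calls in edgeR.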

How the results depend on the processing

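The batch term, equal composition, removal of genes 2 times higher in neurons, removal of the neurons with the most UMIs and thinning of nuclei to 500 UMIs were chosen only after the results were seen; the other alternatives were set beforehand. None of the named genes that passed (at most 20 per class) changed direction under an alternative that gave it an adjusted p. In neurons DESeq2 gave one for only 3 of the 20. The rule for naming genes that passed required groups that do not overlap. That largely fixed their direction when a sample was left out or batch was a term. Named genes that did not pass are left out of this count. Counting each named gene that passed under each alternative with an adjusted p, the call was kept 220 times and lost 100 times in neurons, 152 and 84 in excitatory neurons, 122 and 101 in inhibitory neurons, 155 and 74 in oligodendrocytes, 103 and 58 in astrocytes, 105 and 53 in microglia, 16 and 7 in precursors, 46 and 62 in endothelial cells, and 169 and 71 in all nuclei. DESeq2's size factors left every count within 1.5 times, and neurons gave 123 calls without Scrublet doublets, 124 without ribosomal protein genes, 120 without genes 2 times higher in other nuclei and 128 without the 5% of neurons with the most UMIs. The replicate numbers do not pair the samples: correlations of matching numbers were −0.054, −0.002 and −0.021. The alternative of at least 50 nuclei was not run as a separate count, since among the major cell types it only removes endothelial cells. Mitochondrially encoded genes could not be dropped because they are absent. Depth kept Fosb, Arc, Npas4 and Drd1 out of the tests in neurons.

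The cause of the changes below was not tested. With no filter on low counts there were 250 calls in all nuclei, 335 in neurons, 202 in excitatory and 93 in inhibitory neurons, 270 in oligodendrocytes, 27 in microglia, 8 in precursors, 18 in endothelial cells, 40 in subtypes and 62 for neurons against other nuclei. DESeq2 gave 158 in all nuclei, 44 in excitatory and 11 in inhibitory neurons, 6 in astrocytes, 1 in precursors, 2 in endothelial cells and 8 in subtypes. The batch term, whose calls include genes not called without it, gave 0 in all nuclei, 0 in neurons and 0 in endothelial cells (961, 765 and 29 at unadjusted p under 0.05 in edgeR), 24 in excitatory and 3 in inhibitory neurons, 73 in oligodendrocytes, 3 in astrocytes, 8 in microglia and 1 in precursors. The replicate block gave 4 in inhibitory neurons, 101 in microglia, 12 in precursors and 19 in endothelial cells, and 0 subtypes past the threshold for the immediate early gene level in limma (8 at unadjusted p under 0.05).

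Equal cell type composition gave 208 calls in all nuclei, and equal subtype composition gave 36 in excitatory and 19 in inhibitory neurons. Thinning to the lowest sample total gave 79 in neurons. Without genes 2 times higher in neurons there were 70 in oligodendrocytes (35 higher and 35 lower, 69 of them among the 84 earlier calls still tested), 3 in microglia and 0 in precursors (106 at unadjusted p under 0.05 in edgeR). With limma voom in place of edgeR there were 4 for neurons against other nuclei and 0 for excitatory against inhibitory neurons (575 at unadjusted p under 0.05). Subtypes with 20 or more nuclei in every sample gave 11 gene calls. The immediate early gene level was higher in all 11 such subtypes and passed in 9. Over the 24 subtypes that level passed in 1 subtype with 1 CPM added and in 0 when TMM-normalized (4 at unadjusted p under 0.05 in limma). The immediate early gene list in neurons, with its median of 1.253, lost its call with an estimated correlation and with fry (adjusted p 0.58 and 0.173). The mean AUC was 0.636 with all genes detected in 5% of nuclei, 0.593 with all nuclei of a subtype and 0.506 with logistic regression.

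Leaving out each sample in turn gave 18 to 118 calls in all nuclei, 19 to 105 in neurons, 34 to 89 in excitatory and 2 to 49 in inhibitory neurons, 32 to 164 in oligodendrocytes, 8 to 22 in astrocytes, 1 to 48 in microglia, 2 to 14 in precursors, 0 to 7 in endothelial cells and 13 to 61 in subtypes. It gave 0 to 33 for neurons against other nuclei, 3 to 7 for excitatory against inhibitory neurons, 0 to 16 subtypes past the threshold for the immediate early gene level (15 of the 16 higher), 0 to 1 separated cell type shares (1 without CON 1 and 1 without CON 2) and a mean AUC of 0.458 to 0.625. The immediate early gene list kept its call with the preset correlation, with medians of 0.682 to 1.392, a call that with all samples was lost with an estimated correlation (adjusted p = 0.58) and by fry (adjusted p = 0.173).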

Other observations

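The genes and groups in this part were singled out only after their values were seen; the edgeR tests that gave the p-values were set beforehand.

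The neutrophil genes S100a8 and S100a9 were nearly absent in CON samples. S100a8 rose in all nuclei (edgeR adjusted p = 0.000492), from 0.27 to 10.6 CPM, and so did its partner S100a9 (adjusted p = 0.00131). The UMIs were few and spread over cell types: S100a8 had 2 in neurons of CON and 21 in neurons of TESS samples, and 1 and 49 in other nuclei, among them 0 and 27 in oligodendrocytes, 0 and 14 in microglia, and 0 and 5 in astrocytes. S100a9 had 1 and 26 in neurons and 2 and 33 in other nuclei. The blood and peripheral immune cell list that holds them lost its call with adjusted p = 0.181 with an estimated correlation. Lcn2, listed among reactive astrocyte genes, had 9 UMIs in other nuclei of CON and 48 in those of TESS samples, of which 3 and 32 were in endothelial nuclei.

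Of 11 immediate early genes counted in endothelial nuclei, 8 had a higher CPM in the summed TESS than in the summed CON samples. CPM here are over all UMIs of the summed samples, not over the tested genes as in the endothelial levels above. Egr1 went from 6.24 to 200 CPM (1 and 19 UMIs), Nr4a1 from 6.24 to 221 CPM (1 and 21), Junb from 31.2 to 137 CPM (5 and 13) and Btg2 from 81.1 to 453 CPM (13 and 43). Fos went from 0 to 84.3 CPM (0 and 8 UMIs) and Fosb from 0 to 52.7 CPM (0 and 5). Per1 went from 43.7 to 116 CPM (7 and 11 UMIs) and Sik1 from 68.6 to 116 CPM (11 and 11). Nr4a3 had 1 UMI in CON and 0 in TESS, and Arc and Npas4 had 0 in both. Only Btg2 was abundant enough to test. These counts come from 43, 25 and 62 endothelial nuclei in CON 1, CON 2 and CON 3 and 25, 38 and 28 in TESS 1, TESS 2 and TESS 3.

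Long non-coding genes were counted by annotation, not as a fixed list, and were not tested for enrichment. Of 628 tested in neurons, 69.4% had a change below 0, with a median of −0.23 (−0.336 inside batch 3), and 1 rose while 32 fell. Protein-coding genes had a median of 0.003 over 10,693 tested, with 31 rising and 53 falling. The median of long non-coding genes was −0.29 in oligodendrocytes, where 1 rose and 9 fell, and −0.245 in all nuclei, where 0 rose and 25 fell. It was −0.278 in astrocytes, −0.191 in microglia, −0.262 in precursors and −0.23 in endothelial cells, over 52, 49, 32 and 6 genes. Many of these genes lie antisense to a coding gene, and the strand of counting is not known.

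Among sex-linked genes, Xist stood at 3857 ± 252 CPM in CON and 3173 ± 517 CPM in TESS over all nuclei and did not pass (−0.28 ± 0.13, edgeR adjusted p = 0.332). The Y-linked Ddx3y had 5 to 24 UMIs per sample. Tsix, antisense to Xist, had 2336 UMIs in CON 2 and 161 to 658 in the other samples.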
